A study of Mus musculus with 6 samples.

How the data were processed

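RNA sequencing (RNA-seq) of polyadenylated RNA was performed on left ventricles of male C57BL/6 mice that had received ISO (10 mg/kg/d) or the same volume of saline under the skin for 3 weeks. There were 3 libraries per group, and each library was placed in its group by its sample label. The labels speak of biological repeats without naming single animals, so p-values measure the spread between these samples.

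The deposited values are FPKM (fragments per kilobase of gene length, scaled to the number of mapped fragments) for 21989 gene symbols, in 1 column per library. The submitters' processing notes list CASAVA 1.8, fastp 0.20.0, HISAT2 2.1.0, HTSeq 0.7.2, Cufflinks 2.2.1 and DESeq, and the genome build GRCm38, with no role or order. Which annotation release, which strand setting and which of these tools made the deposited FPKM is not given in the sources used here. Genes that share reads with near-identical copies, such as the globin genes and the histone genes, are therefore uncertain. FPKM divides by gene length and by the library total, so a rise of a few abundant genes lowers all others, and the values do not remove differences in library quality.

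The depth of each library was recovered from the steps of the FPKM values, since a gene's values are whole multiples of what 1 read is worth. Whole reads came out for 100% of the 16816 genes above 0 in at least 2 libraries, within 0.0001 of a whole number. A further 996 genes were above 0 in 1 library only and 4177 were at 0 in all libraries. The recovered library totals were 9862363, 6307039 and 2776152 reads for saline 1 to 3 and 7378782, 5154283 and 5614336 reads for ISO 1 to 3. At these totals, 1 read on a gene of 1 kilobase is worth 0.101 FPKM in saline 1 and 0.360 FPKM in saline 3. On simulated data with known reads for 16816 genes, 98.5% of the genes that gave a recovered value were recovered exactly. Genes that gave no value are not in this share. Confidence intervals (95%, exact Poisson) for reads cover counting error only.

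Values were tested as log2(FPKM + 1), over the 12269 genes with a mean FPKM of at least 1, with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, group as the only term) and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which understates the change of low genes. Gene lists (36, written before the data were examined) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 35 lists that had measured members. The mitochondrially encoded mRNAs were not analysed here. Both steps were tested on simulated data with 12261 genes. At a spread per gene taken from these libraries, 48% of 100 genes changed 4-fold and 87% of 100 genes changed 16-fold were called. Each gene had the same spread in all 6 simulated libraries, while in the data saline 3 stood apart from the others. These shares therefore do not tell how many changed genes the real comparison would call. A list of 30 genes raised 2-fold passed with camera (adjusted p = 1.5e-21), and 30 genes left unchanged did not (adjusted p = 0.871). Genes were drawn independently there, so this cannot show how the list test does when members vary together. In the real lists they did, with an estimated correlation of 0.43 for the oxidative phosphorylation list. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

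Named genes followed a rule written before the data were examined. It took the CPEB and Eif4a genes of the series title, genes past the threshold or otherwise the 5 with the smallest p in each direction, up to 4 members of each list by p, and a fixed set of heart genes. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Gene positions are those of RefSeq on GRCm38.p6, to which 21447 of the symbols were matched by symbol or synonym.

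Before the libraries of a group were averaged, every pair was checked for agreement within sampling noise over genes with at least 50 reads. The pair with the lowest median chi-square, ISO 1 and ISO 2, had 3.86 times the value sampling gives, and the other pairs lay between 9.32 and 43.6 times. This measure depends on depth, but pairs with fewer reads lay higher (11.0 times for saline 2 and ISO 2, 12.0 times for ISO 2 and ISO 3). By Pearson r and by the SD of the log2 ratio the closest pair was saline 1 and saline 2 (r 0.973 and SD 0.54, against r 0.962 and SD 0.66 for ISO 1 and ISO 2). All 6 libraries were counted as separate samples. This check does not tell 2 hearts from 2 pieces of the same heart, and every SD and p-value of the ISO group takes ISO 1 and ISO 2 as separate. Alternatives chosen before the data were examined were other pseudocounts, filters, scalings, sample quality weights, a replicate block, each library left out, another list test and an estimated correlation. Those added after seeing the data were limma-voom on the recovered reads, a comparison with ISO 1 as the only ISO library, quality weights with saline 3 left out, and lists without the genes that separate ISO 2 and ISO 3 from ISO 1.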

Results

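Gene expression was measured in the left ventricle of mice given ISO or saline for 3 weeks. ISO is the usual abbreviation of isoproterenol, a beta-adrenergic agonist, and the labels call the ISO animals a heart failure model. Each group held 3 libraries, with recovered totals of 2776152 to 9862363 reads. Saline 3 had the lowest total, and its Pearson r with the other libraries across genes lay between 0.788 and 0.830, against 0.918 or more among the other 5 libraries. The series title names Cpeb4, a cytoplasmic polyadenylation element binding protein, and the splicing of Eif4a2, an RNA helicase of translation initiation. The comparison asks which genes differ between the ISO and saline ventricles. Splicing was not analysed here, because the values are per gene.

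Matrix, fibroblast, interferon, cytokine, macrophage and red blood cell gene lists were higher in ISO, and heart muscle and mitochondrial energy lists were lower. Of the 35 lists tested, 7 rose and 9 fell with camera (adjusted p under 0.05). No single gene passed the threshold over all 12269 genes tested. None of the 16 calls held with a correlation estimated per list, where adjusted p ran from 0.168 to 0.872. Splits that mix saline and ISO libraries, tried after the results were seen, called 7 to 16 lists with camera. The median log2 fold change of all genes was 0.20, and 0.0057 after median-of-ratios scaling, so a list is compared with this shift and not with 0.

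**Figure D1:**
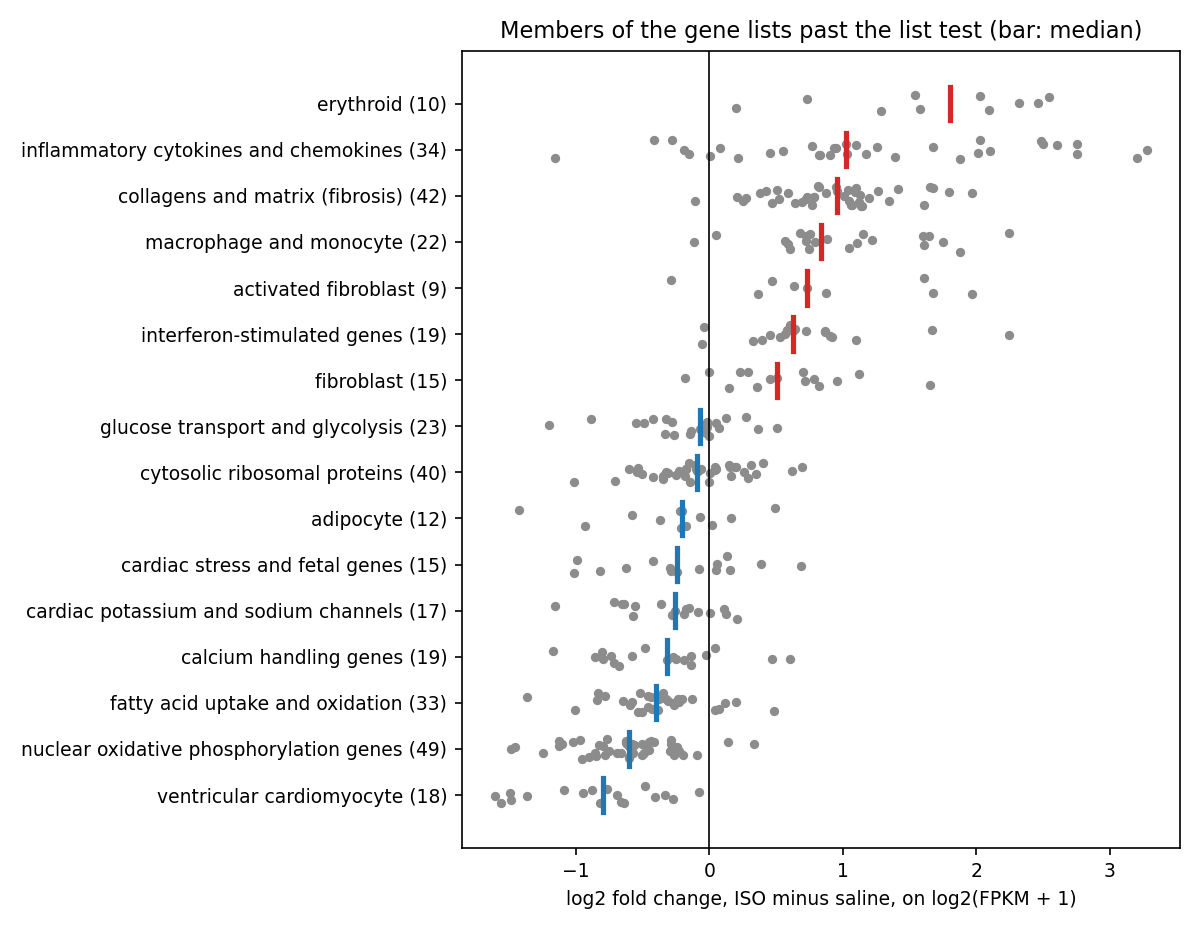
Log2 fold change, ISO minus saline on the log2(FPKM + 1) scale (horizontal axis), of the tested members of the 16 gene lists past the list test (vertical axis, number of members in brackets). Points are genes and bars are list medians, from 1.8 for the erythroid list to -0.79 for the ventricular cardiomyocyte list.

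The collagen and matrix list, which holds the structural proteins of scar tissue, rose (41 of 42 members higher, median log2 fold change 0.95, adjusted p = 1.9e-13, adjusted p = 0.204 with an estimated correlation). Without saline 3 the median was 0.75 and the list still passed. The 3 saline and 3 ISO libraries did not overlap for 25 of the members. Adjusted over the list alone, 9 members rose. Bgn, a small matrix proteoglycan (chromosome X, 73483601 to 73495936), was at 275 ± 8.23 FPKM in saline and 662 ± 62.3 FPKM in ISO (SD, n = 3 each). Lum, a collagen-binding proteoglycan, was at 38.1 ± 4.22 and 83.5 ± 5.13 FPKM. Postn, which activated fibroblasts secrete, was at 32.0 ± 14.1 and 98.9 ± 29.99 FPKM (chromosome 3, 54359267 to 54391041). Col1a1, a chain of type I collagen, was at 72.2 ± 9.21 and 144 ± 40.5 FPKM. Col3a1, a collagen of the same list, was at 142, 177 and 31.7 FPKM in saline 1 to 3 and at 212, 206 and 587 FPKM in ISO 1 to 3. Its log2 fold change of 1.65 (SE 0.71, adjusted p = 0.699 with limma) was 0.89 without saline 3 and 1.16 without ISO 3.

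Fibroblast markers rose (13 of 15 higher, median 0.50, adjusted p = 0.00123), as did activated fibroblast markers (8 of 9 higher, median 0.73, adjusted p = 0.000599). Both had an adjusted p = 0.168 with an estimated correlation. Adjusted over the list alone, 1 fibroblast marker (Lum) and 4 activated fibroblast markers (Ltbp2, Postn, Meox1 and Cilp) rose. Ltbp2, a matrix protein that binds fibrillin, went from 1.81 ± 0.524 to 7.60 ± 1.97 FPKM. Several markers belong to the matrix list as well, so these lists are not independent of each other.

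Macrophage and monocyte markers rose (21 of 22 higher, median 0.83, adjusted p = 4.5e-08, adjusted p = 0.170 with an estimated correlation). Adjusted over the list alone, 5 rose, among them Csf1r, the receptor for macrophage colony-stimulating factor, at 21.7 ± 5.60 FPKM in saline and 49.9 ± 14.8 FPKM in ISO. Fcgr1, an antibody receptor of macrophages, was at 3.24 ± 0.609 and 8.07 ± 0.626 FPKM. Interferon-stimulated genes rose as well (17 of 19 higher, median 0.62, adjusted p = 2.8e-06, adjusted p = 0.186 with an estimated correlation), and 3 of them (Gbp2, Oas1a and Ifit2) rose when adjusted over the list alone. Inflammatory cytokines and chemokines rose as a list (29 of 34 higher, median 1.03, adjusted p = 0.000578, adjusted p = 0.553 with an estimated correlation), with 0 members past when adjusted over the list alone. The cytokine call rested on ISO 2 and ISO 3: with ISO 1 as the only ISO library the median was -0.25 and the list passed in the opposite direction (adjusted p = 0.000498). Without ISO 3 the adjusted p was 0.142, and without saline 2 it was 0.0521.

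Erythroid markers had the highest median of the lists tested. All 10 measured markers were higher (median 1.8, adjusted p = 4.3e-10, adjusted p = 0.168 with an estimated correlation), and 8 rose when adjusted over the list alone. Hbb-bs, an adult beta globin, was at 908 ± 530 FPKM in saline and 4514 ± 212 FPKM in ISO. Alas2, the first enzyme of heme synthesis in red cells, was at 20.3 ± 7.85 and 106 ± 48.1 FPKM. Bpgm, an enzyme of red cell glycolysis, was at 19.5 ± 1.97 and 59.9 ± 17.2 FPKM. Globin genes have near-identical copies, so the split of reads between them is uncertain.

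Ventricular cardiomyocyte markers fell (18 of 18 lower, median -0.79, adjusted p = 1.1e-11, adjusted p = 0.215 with an estimated correlation). The size of the fall rested largely on ISO 3, the library with the lowest Myl2: without it the median was -0.26, and the list still passed. With ISO 1 as the only ISO library the median was -0.24. It was -0.55 without saline 3 and -0.44 with sample quality weights, so ISO 3 was not the only library that set it. Tnnc1, cardiac troponin C, fell when adjusted over the list alone, from 3898 ± 1063 to 1304 ± 263 FPKM (chromosome 14, 31208312 to 31211729). Tnnt2, troponin T, was at 11501 ± 933 and 6776 ± 783 FPKM. Both are among the 12 genes used by both chambers below, so the fall of this list does not show a loss particular to ventricular muscle. Atrial cardiomyocyte markers did not pass (7 of 10 higher, adjusted p = 0.580). In 5 of the 6 libraries the atrial light chain Myl7 was above the ventricular light chain Myl2, genes chosen after their values were seen. The ratio of Myl2 to Myl7 was 0.154, 0.0328 and 1.22 in saline 1 to 3 and 0.172, 0.171 and 0.0168 in ISO 1 to 3.

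**Figure D2:**
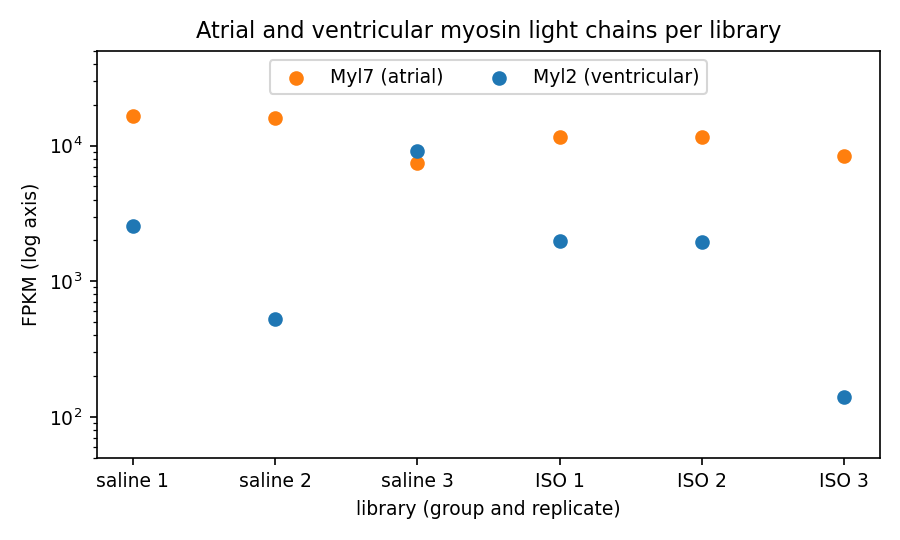
FPKM (log axis) of Myl7, the atrial myosin light chain, and Myl2, the ventricular one, in each of the 6 libraries (1 point per library and gene). Myl2 ran from 140 FPKM in ISO 3 to 9101 FPKM in saline 3.

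Energy metabolism lists fell with the muscle markers. Nuclear oxidative phosphorylation genes fell (47 of 49 lower, median -0.60, adjusted p = 8.6e-26, adjusted p = 0.186 with an estimated correlation), and the groups did not overlap for 24 of them. Without ISO 3 the median was -0.39 and without saline 3 it was -0.46, and the list passed in both. Saline 3 held fewer reads on long genes than saline 1 and 2 did, and the oxidative phosphorylation genes are short (median length 1027 bases, against 3431 for all genes tested and 4205 for the matrix list). Cox8b, a subunit of cytochrome oxidase, was at 1657 ± 412 and 843 ± 137 FPKM. Fatty acid uptake and oxidation genes fell (28 of 33 lower, median -0.40, adjusted p = 7.2e-12, adjusted p = 0.168 with an estimated correlation), with Acot2, a mitochondrial thioesterase, at 16.4 ± 5.45 and 7.44 ± 0.992 FPKM. Calcium handling genes fell (16 of 19 lower, median -0.31, adjusted p = 2.0e-06, adjusted p = 0.168 with an estimated correlation), with Casq2, the calcium store of the sarcoplasmic reticulum, at 261 ± 25.6 and 144 ± 15.4 FPKM. The median of this list was -0.57 without ISO 1 and -0.53 without ISO 2. Cardiac potassium and sodium channels fell as a list (13 of 17 lower, median -0.26, adjusted p = 0.000196, adjusted p = 0.401 with an estimated correlation), and the median was -0.016, -0.15 and -0.52 without saline 1, 2 and 3, -0.47 without ISO 1 and -0.098 without ISO 3, where the list did not pass (adjusted p = 0.0762). In none of these lists did a member pass when adjusted over the list alone.

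The list of cardiac stress and fetal genes, which commonly rise in overloaded hearts, fell (9 of 15 lower, median -0.25, adjusted p = 0.00230, adjusted p = 0.168 with an estimated correlation). Without saline 1 the median was 0.024, so the fall was gone by the median while camera still pointed down (adjusted p = 0.0281), and it was -0.14 without ISO 2 and -0.16 without ISO 3. Its members with the smallest p included Csrp3, a muscle LIM protein, at 1339.99 ± 245 and 669 ± 82.5 FPKM. Myh7, the slow myosin heavy chain, was at 148 ± 9.46 and 85.1 ± 20.6 FPKM, and Myh6, the fast one, at 6183 ± 964 and 3543 ± 857 FPKM. Both had a log2 fold change of -0.82, near the median of the ventricular cardiomyocyte list (-0.79). The shares of muscle and of each chamber in the samples were not separated from a change of these genes with stress. Nppa, the atrial natriuretic peptide, was at 3119 ± 1477 and 3021 ± 817 FPKM, and the sign of its fold change turned under median-of-ratios scaling and with sample quality weights. Nppb was at 164 ± 124 and 120 ± 102 FPKM. Acta1, skeletal alpha actin, had a log2 fold change of -0.29 with all libraries and 1.46 without saline 3, where it stood at 296 FPKM. Quantile normalization ended the call of the list (adjusted p = 0.0809).

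Cpeb4 (chromosome 11, 31870104 to 31935635) was at 4.45, 3.15 and 2.53 FPKM in saline 1 to 3, and at 2.47, 21.8 and 23.6 FPKM in ISO 1 to 3. Its log2 fold change of 1.54 (SE 0.74) did not pass (limma, adjusted p = 0.699), and ISO 1 lay below every saline library. Without ISO 1 the log2 fold change was 2.46, and with ISO 1 as the only ISO library it was -0.31. The 95% counting intervals of Cpeb4 were 2.07 to 2.91 FPKM in ISO 1 and 20.4 to 23.3 FPKM in ISO 2, so depth did not set this gap. Eif4a2 (chromosome 16, 23107468 to 23114132) was at 106 ± 47.4 FPKM in saline and 133 ± 23.9 FPKM in ISO, a log2 fold change of 0.43 (SE 0.39, adjusted p = 0.701) that was 0.013 without saline 3 and 0.73 without saline 1. Eif4a1 had a log2 fold change of 0.22, which was -0.0011 without ISO 3, 0.11 without saline 3 and 0.44 without ISO 1. Eif4a3 had a log2 fold change of -0.25, which was -0.13 without saline 3. Cpeb1, Cpeb2 and Cpeb3 had log2 fold changes of 0.84, 0.13 and -0.26, and each turned sign when 1 saline library was left out. Cpeb1 was listed at 0 in saline 3. The CPEB and translation initiation list did not pass (22 of 33 higher, adjusted p = 0.992).

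**Figure D3:**
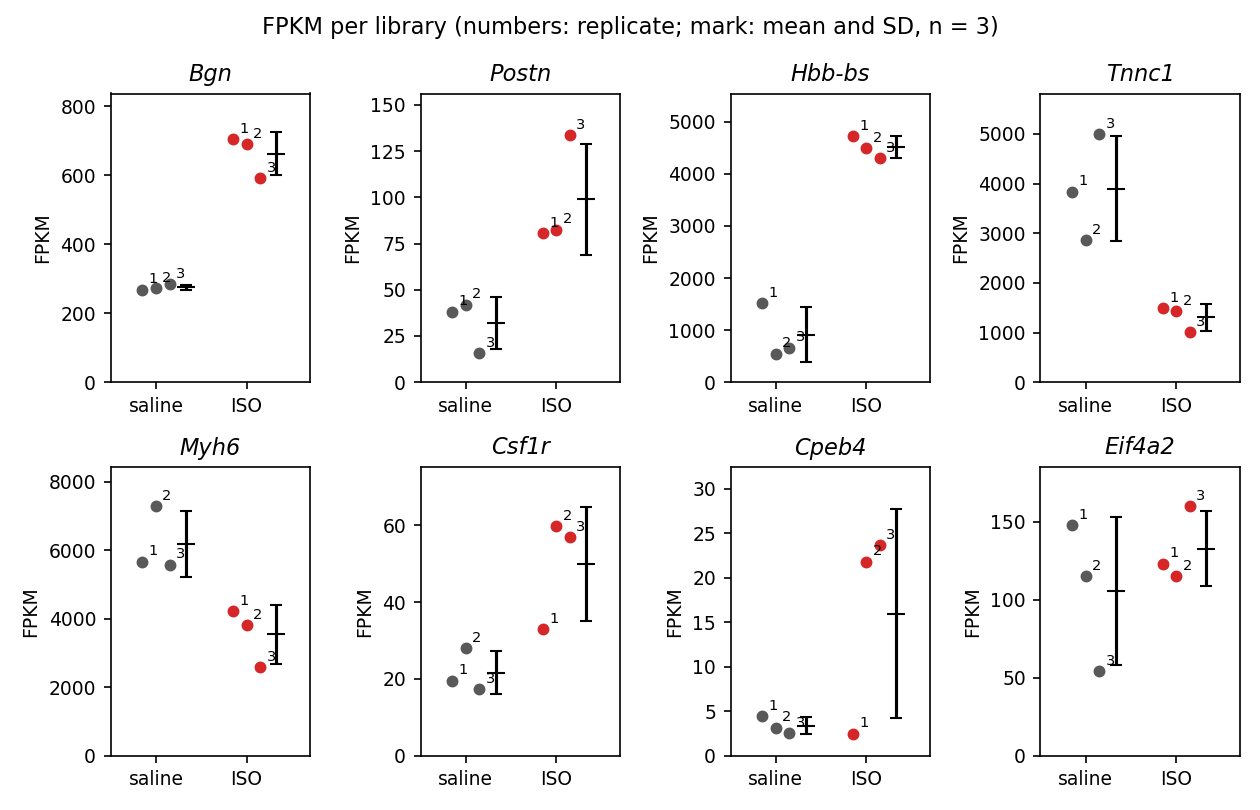
FPKM (vertical axes, from 0) of 8 named genes in the 3 saline and 3 ISO libraries (horizontal axes; points are libraries with their replicate number, marks are the mean and SD). Bgn lies between 268 and 284 FPKM in saline and between 591 and 705 FPKM in ISO, while Cpeb4 in ISO 1 (2.47 FPKM) lies with the saline libraries.

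The lists on cell death and division did not pass. Pro-apoptotic genes had 23 of 28 members higher (adjusted p = 0.618) and anti-apoptotic genes 13 of 14 (adjusted p = 0.153). Bax, which permeabilizes mitochondria, was at 29.6 ± 6.61 and 31.9 ± 8.05 FPKM. Bcl2, which opposes cell death at mitochondria, was at 2.27 ± 0.455 and 2.68 ± 1.01 FPKM. Proliferation genes had 19 of 25 members higher (adjusted p = 0.194). Mki67, a marker of dividing cells, was at 1.44 ± 0.585 and 6.81 ± 3.69 FPKM with no overlap of the groups, and did not pass (adjusted p = 0.699). Cell cycle inhibitors had 12 of 16 members higher (adjusted p = 0.371), with Cdkn1a at 9.79 ± 1.59 and 24.6 ± 7.42 FPKM.

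The glycolysis list (17 of 23 lower, median -0.072, adjusted p = 0.00173) and the adipocyte markers (9 of 12 lower, median -0.21, adjusted p = 0.0257) fell. With an estimated correlation they had an adjusted p = 0.215 and an adjusted p = 0.648. The glycolysis call was lost with quality weights (adjusted p = 0.406), with quantile normalization (adjusted p = 0.0690) and without ISO 3 (adjusted p = 0.125, median 0.11), and the median was 0.050 with values rescaled to a common sum. Its median was -0.16, -0.12 and -0.025 without saline 1, 2 and 3, and -0.19 without ISO 1 or ISO 2. The adipocyte call was lost with quantile normalization (adjusted p = 0.156), with no filter (adjusted p = 0.0784) and without saline 2, saline 3, ISO 1 or ISO 2 (medians -0.027, -0.33, 0.056 and -0.019). The adipocyte median was -0.48 without saline 1 and -0.71 without ISO 3. Cytosolic ribosomal protein genes passed as lower (24 of 40 lower, median -0.094, adjusted p = 0.0145, adjusted p = 0.872 with an estimated correlation), and this direction turned without saline 3 (median 0.24). The ribosomal median was -0.24, -0.27 and -0.17 without saline 1, saline 2 and ISO 1, and the call was lost without ISO 3 (median -0.054, adjusted p = 0.144), with no filter (adjusted p = 0.0784) and with values rescaled to a common sum (adjusted p = 0.0530). The remaining lists did not pass. Their adjusted p was 0.0602 for circadian clock genes, 0.978 for splicing factors, 0.506 for beta-adrenergic signalling, 0.552 for the unfolded protein response, 0.655 for oxidative stress and 0.995 for immediate early genes. It was 0.361 for endothelial, 0.0725 for mural, 0.254 for lymphocyte, 0.992 for neutrophil, 0.945 for Schwann cell, 0.945 for epicardial and 0.259 for skeletal muscle markers. Gzmb, a granule protease of killer lymphocytes, rose when adjusted over the list alone (log2 fold change 1.36). It rested on few reads: 14, 2 and 0 in saline 1 to 3 and 24, 18 and 21 in ISO 1 to 3. Of the 18 lymphocyte markers, 7 were tested. For 6 lists that did not pass (CPEB and translation, beta-adrenergic, unfolded protein, oxidative stress, atrial and neutrophil) the median was above 0 while camera pointed down. Adrb1, the main beta-adrenergic receptor of the heart, was at 2.47 ± 2.18 and 1.82 ± 0.787 FPKM.

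Across all genes, limma called 0 at adjusted p 0.05 (smallest adjusted p 0.699), 774 genes had an unadjusted p under 0.05 (604 higher and 170 lower), and chance gives 613. The groups did not overlap for 2028 genes (16.5%, where chance gives 10%). The genes with the smallest p, none of which passed, included Angptl7, Hist1h4n, Hbb-bs, Bgn and Bpgm among those higher and Ttr, Tnnc1, Aldoc and Rilp among those lower. Angptl7, a secreted angiopoietin-like protein, was at 2.79 ± 0.205 and 17.6 ± 5.60 FPKM, and Rilp, a lysosome transport protein, at 46.9 ± 1.86 and 25.9 ± 1.57 FPKM. Sample quality weights, which give saline 3 a weight of 0.0772 and ISO 2 a weight of 5.50, called 768 genes (521 higher and 247 lower), limma-voom called 0, and the fit without ISO 1 called 16.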

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

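Alternatives named in this part as added were chosen after the data were seen; the others were chosen before. Calling 0 genes past the threshold held under every alternative except sample quality weights (768 genes, of which 497 had groups that did not overlap) and the fit without ISO 1 (16 genes, all higher), so leaving out 1 library gave 0 to 16. Quality weights with saline 3 left out (added) called 0 genes with the 5 remaining libraries. The 16 lists became 0 with an estimated correlation, so the calls depend on which form of camera was used. A larger correlation was not the reason for every lost call. The estimate was -0.025 for the cardiac stress list, 0.016 for fibroblast and 0.020 for activated fibroblast markers, near or below the preset 0.01. Fry, a different test that sets each list against no change and not against the other genes, passed 4 (3 higher and 1 lower). Quantile normalization kept 12 of the 16 and added 0, and quality weights kept 14 and added 4. Leaving out 1 library gave 15 to 18 lists. They were 16 kept and 0 new without saline 1, 14 and 1 without saline 2, and 14 and 3 without saline 3. They were 15 and 3 without ISO 1, 15 and 1 without ISO 2, and 12 and 3 without ISO 3. A list that passed in the reversed direction is in neither number, as the ribosomal protein list was without saline 3 and with quality weights. With ISO 1 as the only ISO library (added) 13 were kept and 6 were new. The replicate block called 0 genes and 16 lists. Same-numbered libraries did not deviate together (correlations 0.013, -0.15 and -0.025), and not every library correlated best with its own number. No pairing by number was seen. With 3 libraries per group and saline 3 far from the others, this check cannot exclude a shared litter or batch. Lists without the 82 genes that separate ISO 2 from ISO 1 (added) gave 16 calls. The median log2 fold change of all genes ran from -0.0031 with quantile normalization to 0.33 with values rescaled to a common sum per library. Depth limits saline 3 most, where 1 read on a gene of 1 kilobase is worth 0.360 FPKM.

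None of the named genes below had passed, and the cause of their turns was not tested beyond the libraries named. With ISO 1 as the only ISO library (added; it is assumed to vary like the saline libraries), the log2 fold changes that turned sign were -0.19 for Cpeb2, 0.069 for Cpeb3, -0.31 for Cpeb4, -0.23 for Eif4a1, -0.54 for Bcl2a1b, -0.15 for Txnrd1, 0.013 for Stard10, -0.18 for Nppa, -0.16 for Bax, -3.77 for Cxcl2, -2.39 for Ccl3, -2.15 for Acod1, -1.15 for Il1b, -1.40 for Hmox1, -1.30 for Clec4e, -1.86 for Col2a1, -0.77 for Acan, -0.82 for Col9a1, -1.17 for Col11a1 and 0.20 for Irx4. The medians of 3 lists turned: -0.25 for the cytokine list, 0.019 for the glycolysis list and 0.0055 for the ribosomal protein list, and the list test turned for the cytokine list alone. Sample quality weights gave -0.56 for Cpeb1, -0.28 for Cpeb2, -0.19 for Eif4a2, -0.048 for Retnlg, -0.15 for Sox10, -0.63 for Nppa, 1.63 for Acta1 (adjusted p = 0.0370, and 0.0370 to 1 over its alternatives), -0.055 for Ankrd1, -0.064 for Bax, -0.12 for Bcl2, 0.17 for Myl3, -0.59 for Sln, -0.020 for Timp1 and 0.25 for the ribosomal protein list. With saline 3 also left out (added) the values were -0.58 for Cpeb1, -0.22 for Cpeb2, -0.13 for Eif4a2, -0.048 for Dkk3, -0.095 for Retnlg, -0.19 for Sox10, -0.54 for Nppa, 1.58 for Acta1, -0.18 for Ankrd1, -0.16 for Bax, -0.18 for Bcl2, 0.54 for Myl2, 0.67 for Myl3, -0.032 for Myl4, -0.52 for Sln, 0.16 for Irx4, -0.080 for Timp1, 0.27 for the ribosomal protein list and 0.095 for the glycolysis median.

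Median-of-ratios scaling gave -0.016 for Cpeb2, -0.014 for Eif4a1, -0.18 for Nppa, -0.12 for Bax, -0.018 for Bcl2, -0.11 for Myl4 and -0.11 for Sln. Quantile normalization gave -0.17 for Cpeb2, -0.024 for Bax, -0.12 for Bcl2, 0.31 for Myl7 and 0.12 for the ribosomal protein list. Adrb1 was 0.30 and 0.47 with pseudocounts of 0.1 and 0.01 and 0.072 with values rescaled to a common sum, where the medians of the glycolysis and ribosomal protein lists were 0.050 and 0.028. Limma-voom on recovered reads (added) gave -0.059 for Cpeb2 and 0.30 for Acta1. Leaving out 1 library at a time turned the sign of the following, with their ranges: the ribosomal protein list (-0.27 to 0.24), the cardiac stress list (-0.29 to 0.024), the glycolysis list (-0.19 to 0.11), the adipocyte list (-0.71 to 0.056), Cpeb1 (-0.29 to 1.45), Cpeb2 (-0.20 to 0.37), Cpeb3 (-1.02 to 0.39), Eif4a1 (-0.0011 to 0.44), Dkk3 (-0.022 to 1.61), Bmp10 (-0.22 to 2.14), Nppa (-0.38 to 0.38), Nppb (-1.22 to 0.38), Acta1 (-1.32 to 1.46), Adrb1 (-0.73 to 0.40), Bax (-0.090 to 0.26), Bcl2 (-0.064 to 0.31), Myl4 (-0.35 to 0.50), Sln (-0.55 to 0.57), Irx4 (-0.79 to 0.29) and Timp1 (-0.0074 to 2.73). Outside the fits that left out 1 library at a time, 1960 results for named genes kept their direction and side of the threshold and 55 passed it in the same direction. For lists, where direction is that of the list test and not of the median, 214 kept both and 38 no longer passed; these counts include the medians above that turned while the test did not.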

Other observations

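The tests of explanations below were chosen after the results were seen, including the comparison with other splits of the samples.

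Several genes of other tissues were high in 1 to 3 of the 6 libraries (chosen after their values were seen). Cartilage collagen Col2a1 was at 41.4 FPKM in saline 2, 64.7 FPKM in ISO 2 and 70.8 FPKM in ISO 3, at 0.138 FPKM in saline 1, and listed at 0 in saline 3 and ISO 1. Acan, the cartilage proteoglycan, was at 5.07, 10.2 and 9.86 FPKM in saline 2, ISO 2 and ISO 3, and at 0.105 FPKM or less in the other 3 libraries. The liver gene Alb was at 306 FPKM in saline 3 and between 1.91 and 16.4 FPKM elsewhere. The airway gene Scgb1a1 was at 201 FPKM in saline 3 and 182 FPKM in ISO 3, and between 0.869 and 13.2 FPKM in the other libraries. The clock genes Nr1d1 and Dbp had log2 fold changes of -1.61 and -1.18, and neither they nor their list passed.

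ISO 1 and ISO 2 had the lowest median chi-square of all pairs (3.86 times the sampling value, next saline 1 and saline 2 at 9.32), a measure that depends on depth. They were not the closest by Pearson r (0.962, against 0.973 for saline 1 and saline 2, 0.967 for saline 1 and ISO 1 and 0.966 for saline 2 and ISO 1). Nor were they by the SD of the log2 ratio (0.66, against 0.54, 0.61 and 0.59 for the same pairs), so the measures disagree. Their ratios of Myl2 to Myl7 were 0.172 and 0.171. Of the genes with at least 50 reads in the pair, 8.85% lay beyond 4 counting SDs, which is above sampling noise, so they were kept as 2 samples. Pieces of a single heart could differ by as much, so these values show neither 1 heart nor 2. If they came from 1, the ISO group holds 2 animals, and its SDs and p-values are too small. Without ISO 1, limma called 16 genes and 18 lists, and without ISO 2 it called 0 genes and 16 lists.

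The first pattern is a set of 82 genes that were at least 8-fold higher in ISO 2 than in ISO 1, among them Cpeb4, the activated macrophage genes Cxcl2 and Acod1, and the cartilage genes Col2a1, Acan, Col9a1 and Col11a1; they took 1.22% of the reads in ISO 2 and 1.22% in ISO 3, against 0.0405% in ISO 1 and 0.106 to 0.131% in saline. More resident macrophages as the whole source of an 8-fold rise are argued against. The macrophage markers rose from ISO 1 to ISO 2 by a median log2 of 0.50 (bootstrap 95% interval 0.14 to 0.86), where an 8-fold rise needs 3. A smaller rise of macrophages is not excluded, and the interval covers only the spread of members in this pair of libraries. Of the 22 markers, 2 rose more than 8-fold, among them Cd14 (log2 3.31), which is also 1 of the 82 genes. The 82 genes were picked for their rise in this pair, and the markers were not. RNA from outside the heart muscle that reached ISO 2 and ISO 3 at the same level may account for part of the pattern. The median absolute deviation of log2(ISO 3 / ISO 2) was 0.134 over these genes, below all of 1000 sets of like read number (median 0.311, lowest 0.196). A like response in 2 ISO hearts is not excluded by this. The set also holds Hnrnpu, Eif5a, Ppp1ca and Bag6, which are not markers of an outside tissue. These genes were not tested apart from the others. Whether the set has 1 source or more was not tested: Col2a1 moved with it between ISO 2 and ISO 3 (log2 0.13), while saline 2 held Col2a1 at 41.4 FPKM with Cxcl2 at 0.586 FPKM. No rise in ISO 1 was seen that a response of all 3 ISO hearts would need. The cytokine list had a median log2 of -0.25 with ISO 1 as the only ISO library. Every other alternative of the list had a median above 0, with a list test adjusted p of 1.7e-16 to 0.553. In ISO 1, 9 of 34 members lay above every saline library, where chance gives 8.5. The bootstrap 95% interval over members, -0.92 to 0.32, holds 0 and leaves a small rise open. This list shares members with the 82 genes, among them Ccl3. Its low values in ISO 1 are thus partly set by how those genes were chosen.

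The second pattern is the spread of ventricular light chains. ISO as the only cause is left open: log2 Myl2 ranged over 4.11 within saline while the group means differed by -1.49 (2.29 and -0.50 without saline 3), but without saline 2 the range was 1.83 and the difference -2.56, and without ISO 3 the difference was -0.23. Different shares of atrial and ventricular muscle in the dissected pieces may account for it: over the 6 libraries, Myl2 and Myl3 ran against the 10 atrial markers, both relative to 12 genes used by both chambers (Pearson r -0.820, exact permutation p = 0.0139, and r -0.743 without saline 3). In ISO 3, Myl7 (8354 FPKM) was low together with the lowest Myl2 (140 FPKM), which a higher atrial share alone would not give, and a change of these genes within muscle cells was not tested. The labels give the left ventricle for every sample.

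The third pattern is saline 3, a single library for which no biological explanation was tested. Its lower depth alone is argued against, since 141 of 10745 genes with at least 20 expected reads had 0 reads, while the other 5 libraries, thinned at random to its depth and predicted from their own group, had at most 40 (ISO 1, 100 draws each), and at most 9 apart from ISO 1. A length trend was present (median log2 ratio to saline 1 and 2 of 0.19 in the shortest sixth of genes and -0.83 in the longest, Spearman rho -0.298 across genes), in the direction of the lower short oxidative phosphorylation genes and the higher long matrix genes in ISO, whose lists passed without saline 3 as well. Loss of reads from long genes is argued against as the whole cause: after the length trend was removed, the SD of its log2 ratio to the other saline libraries was 2.97 times that of saline 2 against saline 1. Whether few starting molecules account for the scatter was not decided. Around the median ratio to saline 1 and 2, 6.81% of genes lay more than 2 log2 units low in saline 3 and 2.52% more than 2 high. For saline 2 against saline 1 the shares were 0.0960% and 0.108%. Any wide scatter that goes both ways gives such shares, whatever its source, so this test cannot tell sources apart. Saline 3 also held genes of other tissues, such as Alb at 306 FPKM, and a different tissue content was not tested.

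The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes and the highest other 5, so 10 of the 10 splits gave as many. With a real count of 0 this outcome was fixed in advance and tells nothing. The real split had 774 genes at unadjusted p under 0.05 in limma and the highest other 566 (1 of 10 as large). It called 16 lists and the highest other 16 (2 of 10), that of saline 1, saline 2 and ISO 1 against the rest. The lowest other called 7, so lists passed with camera at the preset correlation in every split. With sample quality weights the real split called 768 genes and the highest other 261 (1 of 10).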
